A study of Mus musculus with 4 samples.

How the data were processed

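Live CD45-positive cells were sorted from mouse mammary tumours after intratumoral injection of control plasmid or IL-12 plasmid and electroporation, per the labels, with 3 mice pooled per treatment. Each pool gave 1 gene expression library from transcript 5′ ends and 1 T cell receptor library, per the labels. The submitters' processing notes name Cell Ranger 2.1.0 and STAR 2.6.1 with the mm10 genome, and Partek for later steps, whose version is not given in the sources used here. The authors deposited, for each expression library, a table of cells by 11407 genes whose values are log2 of counts per 1000000 plus 1, with the authors' cluster, class and receptor columns; this scale was read from the values themselves. The receptor cell table, also deposited by the authors, holds score values for gene sets and cell cycle phases per cell; how the authors made each score is not given in the sources used here, and only differences between group means and SDs are printed. A column of the expression tables called a total count is the sum of a cell's log2 values and was not used as a depth.

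UMIs were recovered per cell by undoing the logarithm and taking the smallest value of a cell above 0 as 1 UMI, and the recovered values were whole numbers within 0.1 for all but 6 of 4251108 control values and 13 of 13883686 IL-12 values. The total UMIs of a cell follow from that value and include genes outside the table; the table's genes held 72.9% of control and 70.4% of IL-12 UMIs. Cells ranged from 655 to 19573 UMIs in the control library and from 766 to 19603 in the IL-12 library. The tables hold 0 ribosomal protein genes and 11 mitochondrial genes, with a median mitochondrial share of 1.15% in control and 1.10% in IL-12 and highest values of 9.85% and 9.98%. Cells of the receptor table were joined to the expression tables by barcode: 3793 of 3793 were found, 3793 had the same class and 3780 the same cluster. A clone was recorded in the expression tables for 3787 of them, and whether the clones were the same was not compared. A group column of that table gives IL-12 for all 3793 cells, while its library column gives 483 control and 3310 IL-12 cells; the library column was used.

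Groups follow the labels. With 1 library per treatment, cells are not replicates, so no test, p-value or count of differing genes was made from cells. Shares have exact binomial 95% intervals, and folds and levels have exact Poisson 95% intervals from summed UMIs; both cover counting error only. Gene levels are summed UMIs over the cells of a class, scaled to the total UMIs of those cells (CPM), and log2 ratios carry a pseudocount of 1 CPM. A gene without UMIs in 1 library has a lower bound of the fold, computed against a floor of 3 counts over the class. A gene counted as measured with at least 50 UMIs over both libraries and a UMI in at least 5% of the cells of either. The methods were run on simulated data: of 1697 genes 95.0% had intervals that held the true ratio. All cells of a simulated library had the same expression profile. The simulation therefore checks the computation only, not the intervals of genes whose UMIs lie in few cells, nor differences between mice.

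Cell classes are those of the authors. Each cluster was checked by whether its 10 genes with the largest excess over other cells (a UMI in at least 10% of its cells, pseudocount 10 CPM) held fewer markers of its own type than of others, over 21 marker lists. Cluster 8 did so over both libraries and cluster 13 within the IL-12 library (over both it held 3 of each), so values of these are also given, or given alone, by cluster number. Clusters 2 and 11 held no marker of any type over both libraries. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Gene levels were compared in all sorted cells and in classes with at least 50 cells in both libraries, with cluster 13 in place of the class called B cells. For the shares of cells with a UMI of CXCR3 axis genes and for the shares called thinned, each cell was thinned at random to 1000 UMIs, and shallower cells were left out. All other shares of cells with a UMI are over all cells at their full depth.

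The genes named are the 10 with the largest and the 10 with the smallest log2 ratio among measured genes in all sorted cells, CD8 T cells, CD4 T cells, macrophages and neutrophils, and 3 each way in cluster 13. Receptor segments, immunoglobulin, mitochondrial and ribosomal protein genes were left out of these ranks. Up to 4 examples per gene list were named, and Ifng, Gzmb, Cxcr3, Cxcl9, Cxcl10, Cxcl11, Il12a, Il12b, Cd8a, Cd4, Pdcd1 and Cd274 in any case. Some genes that this rule names are not reported here. The 19 gene lists cover the CXCR3 axis, the interferon-gamma and type I interferon responses, MHC class I and class II presentation, cytotoxic effectors, IL-12 signalling and Th1, Th2 and Th17, T cell exhaustion, naive and memory T cells, regulatory T cell genes, proliferation, classically and alternatively activated macrophages, neutrophil and suppressor myeloid genes, T cell attracting chemokines, costimulation and checkpoint ligands, dissociation stress and haemoglobin. Members with at least 20 UMIs counted as higher or lower from 1.5-fold, and the median log2 ratio of measured members was placed among 10000 random lists of measured genes of like level, as a percentile and not as a test. The comparisons, lists, thresholds and naming rule were fixed before the data were examined.

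Own clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method, at resolutions 1, 0.5 and 2, with both libraries together, and at resolution 1 with each library alone. Doublets were called with Scrublet at an expected rate of 6% within each library; 2 control cells and 570 IL-12 cells (4.39%) were called, at score thresholds of 0.570 and 0.209. Receptor clones are those of the authors, expanded meaning 2 or more cells, and 1000 draws without replacement equalised cell numbers, over all receptor cells and, chosen after the data were seen, within the CD8 class and for clones from the beta chain. Shared sequence was measured as the percent of a gene's 60-base stretches found in another gene of the GENCODE annotation vM21 (mm10), which also gave gene positions. Alternatives covered scaling (trimmed mean of M-values and median-of-ratios scaling, both coded for this purpose; totals without mitochondrial, haemoglobin and receptor genes), cell means in place of sums, pseudocounts of 0.1 and 10 CPM, no filter on measured genes, a filter of 500 UMIs and 10% mitochondrial UMIs, doublets left out, other clusterings, classes from marker UMIs, a denominator without neutrophils, reweighting to control class shares, thinning to 2000 UMIs or none, expanded clones from 3 cells, clones from the beta chain alone, T cell classes alone, CD4 T cells with a receptor alone, and the class called B cells in place of cluster 13. Seeds were fixed at 1. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.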

Results

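Immune cells were sorted from mouse mammary tumours that had received an intratumoral injection of control plasmid or of a plasmid for interleukin 12 (IL-12), each followed by electroporation. IL-12 is a cytokine that drives T cells and NK cells towards interferon-gamma production. The labels give the sort as live CD45-positive cells, CD45 being carried by nearly all leukocytes. Cells of 3 mice were pooled per treatment, and each pool gave 1 gene expression library and 1 T cell receptor library, so no difference between the treatments has a replicate check and no test was made. The labels differ on the tumour model: the title and design text name triple-negative breast tumours, the library names in the tables name the 4T1 line, a mammary carcinoma line of BALB/c mice, and the growth protocol describes induction of HER2 in mammary tissue. The model is called mouse mammary tumours here. The control table held 4232 cells with 17306854 unique molecular identifiers (UMIs) and a median of 3021 UMIs per cell. The IL-12 table held 12979 cells with 59956933 UMIs and a median of 3418 per cell. A median of 819 genes was seen per cell in the control library and 871 in the IL-12 library. Brackets after a share or a fold give its exact 95% interval, which covers counting error only, not the difference between mice or between preparations.

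The composition of the sorted cells was compared because the title speaks of an expansion of CD8 T cells, the cytotoxic T lymphocytes. Cells that the authors call CD8 T cells made up 15.3% (14.3 to 16.5) of the control library and 25.1% (24.4 to 25.9) of the IL-12 library. Cells called CD4 T cells, by name the helper and regulatory lineage, stood at 4.23% (3.64 to 4.88) and 7.69% (7.24 to 8.16). This difference of 3.46 points turned to -1.05 with each library clustered on its own and to -0.156 with classes from marker UMIs. It was 0.480 to 0.908 points with clusters made here from both libraries. Neutrophils were the most frequent class in both libraries, at 64.3% (62.8 to 65.7) in control and 45.5% (44.7 to 46.4) in IL-12. Macrophages made up 13.6% and 13.1%, and 12.2% in both libraries with clusters made here at resolution 0.5, but 13.5% and 18.9% at resolution 1, 13.4% and 19.4% at resolution 2, and 15.1% and 19.4% with each library clustered on its own. Cells called B cells made up 2.24% and 2.04%. Cells called dendritic cells (DCs) numbered 14, or 0.331% (0.181 to 0.554), in the control library and 842, or 6.49% (6.07 to 6.92), in the IL-12 library; with clusters made here at resolution 1, DCs were 0.473% and 1.12%. The share of 1 class in a sort depends on the yield of all others. Among the 1511 control and 7071 IL-12 cells that are not neutrophils, CD8 T cells were 43.0% and 46.2%, CD4 T cells 11.9% and 14.1%, macrophages 38.0% and 24.1%, and cells called DCs 0.927% and 11.9%. The difference in the CD8 share, 9.81 percentage points over all cells, was 3.21 points without neutrophils.

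**Figure D1:**
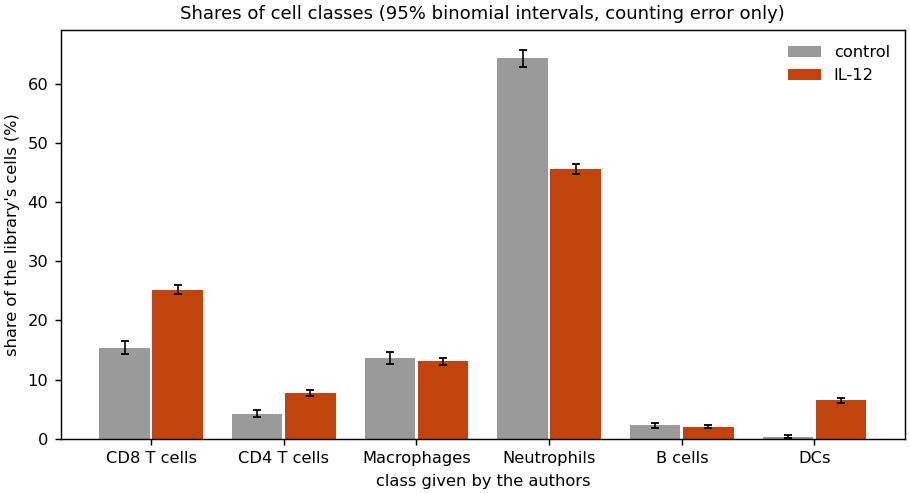
Share of each library's cells (percent, vertical axis) in the 6 classes given by the authors, for the control library (grey) and the IL-12 library (orange); error bars are 95% binomial intervals that cover counting error only. Neutrophils stand at 64.3% and 45.5%, CD8 T cells at 15.3% and 25.1%.

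The ratio of CD8 to CD4 T cells leaves out the myeloid classes, but its CD8 class includes cluster 12, whose cells also carried neutrophil transcripts. By the authors' classes the ratio was 3.63 (3.07 to 4.30) in the control library and 3.27 (3.05 to 3.51) in the IL-12 library. Its direction depended on how the classes were drawn. With Cd8a or Cd8b1 against Cd4 UMIs in cells with a T cell transcript, it was 7.77 in control and 19.6 in IL-12. With clusters made here at resolution 0.5 it was 4.93 and 9.37, at resolution 2 it was 4.55 and 7.17, and with each library clustered on its own it was 3.57 and 9.92. The authors' CD4 class held a Cd8a UMI in 45.8% (38.4 to 53.4) of its control cells and 51.4% (48.2 to 54.5) of its IL-12 cells, against a Cd4 UMI in 17.3% (12.1 to 23.7) and 11.4% (9.51 to 13.6). In neutrophils, which should lack both transcripts, a Cd8a UMI was seen in 1.32% and 4.94% and a Cd4 UMI in 0.147% and 0.152%. Median depths were 2784 and 2590 UMIs in the CD4 class and 2524 and 2553 in neutrophils. Over both libraries, clusters made here placed 26.9%, 38.0% and 30.4% of the authors' CD4 class with CD4 T cells at resolutions 0.5, 1 and 2. They placed 65.5%, 55.7% and 63.5% of it with CD8 T cells. Levels given below for CD4 T cells are those of the authors' class.

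Over all sorted cells, transcripts of interferon-gamma and of the CXCR3 pathway stood higher in the IL-12 library. Ifng, the gene of interferon-gamma, was at 23.7 UMIs per 1000000 (CPM) in control and 129.1 in IL-12, a 5.45-fold difference (4.93 to 6.03). Cxcl9, which encodes a chemokine that attracts cells bearing the receptor CXCR3, was 3.56-fold higher (3.14 to 4.06), Cxcl10, a second ligand of that receptor, 2.13-fold higher (1.97 to 2.30), Cxcl11, a further ligand, 1.63-fold higher (1.43 to 1.86), and Cxcr3 itself 3.62-fold higher (2.75 to 4.86). Chil3, a chitinase-like protein of activated myeloid cells, was 9.83-fold lower (9.43 to 10.3) in the IL-12 library. Of the subunits of the cytokine that the plasmid encodes, Il12b had 7 UMIs in control and 368 in IL-12, 15.2-fold more by CPM (7.29 to 38.0), and Il12a had 172 and 336 UMIs, 1.77-fold fewer by CPM (1.47 to 2.14). Whether any of these UMIs came from the plasmid was not tested.

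The genes that ranked highest in all sorted cells were Mcpt2 and Mcpt1, mucosal mast cell proteases, at 34.9-fold (25.8 to 48.4) and 11.5-fold (9.96 to 13.4). Of the IL-12 library's UMIs of these genes, 71.8% lay in 8 of its 12979 cells. Mcpt2 and Mcpt1 were followed by Tpt1-ps6 at 9.25-fold, Gpx4, a lipid peroxide reductase, at 9.01-fold, Atp6v0c-ps2 at 8.10-fold, Rbx1-ps at 8.35-fold, Zbed5 at 7.42-fold, H2-T10 at 7.30-fold, Ly6c2, a marker of inflammatory monocytes that activated T cells also carry, at 6.76-fold and Ly6a at 5.62-fold. Of these, 85.2% of the 60-base stretches of Atp6v0c-ps2, 48.5% of those of Rbx1-ps, 46.1% for Tpt1-ps6, 32.7% for Gpx4 and 25.1% for H2-T10 occur in another annotated gene, so the counts of these genes are uncertain. The lowest after Chil3 were Crispld2, 7.42-fold lower, AC160336.1, 6.27-fold lower, Mmp8, a neutrophil collagenase, 5.52-fold lower (5.26 to 5.80), Mustn1, Dach1, Klhl2, Stfa3, Fbxl5 and Retnlg, a resistin-like protein of neutrophils, 4.45-fold lower (4.38 to 4.51).

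Each gene list fixed beforehand was described by the members with at least 20 UMIs that differed by 1.5-fold or more, and by the median log2 ratio of its measured members. Of the lists with at least 2 measured members, 9 of 17 lay at or above percentile 95 of random lists of like expression and 2 at or below percentile 5 in all sorted cells, 7 and 0 of 17 in CD8 T cells, 5 and 2 of 16 in CD4 T cells, 13 and 2 of 17 in macrophages, 9 and 3 of 14 in neutrophils and 7 and 2 of 17 in cluster 13. The median of all 5366 measured genes was -0.11 in all sorted cells. All 4 members of the CXCR3 list were higher, with a median of 1.42 over its 2 measured members, at percentile 99.8. In the type I interferon response 10 members were higher, 2 lower and 2 within 1.5-fold (median 0.80), with Ifit3 2.80-fold, Ifit2 2.71-fold and Usp18 2.28-fold higher. The interferon-gamma response had 7 higher, 2 lower and 13 within that range (median 0.28): the GTPases Iigp1 and Gbp4 were 3.82-fold and 3.32-fold higher and Nos2, the inducible nitric oxide synthase, 2.57-fold lower (2.42 to 2.73). MHC class I genes were higher in 5 cases and lower in none of the 11, with H2-K1 2.30-fold and B2m 2.20-fold higher. MHC class II genes were higher in 4 and lower in 1 of 10, with H2-Eb1 at 2.05-fold and Cd74 at 1.93-fold. The chemokines that attract T cells had 7 higher and none lower of 10, led by Ccl5 at 4.55-fold (4.47 to 4.63) and Ccl8 at 3.06-fold.

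T cell lists mostly stood higher over all sorted cells, where the T cell share was also larger. Of the 12 cytotoxic effector genes 10 were higher and 1 lower (median 1.08), with Nkg7 3.09-fold and Gzmk 3.02-fold higher. Exhaustion genes, mostly inhibitory receptors of chronically stimulated T cells, were higher in 5 and lower in 2 of 10, with Tigit at 2.85-fold and Pdcd1, the gene of PD-1, at 2.13-fold (2.04 to 2.22). The regulatory T cell list had 4 higher and 1 lower of 10, the IL-12 signalling list 3 higher and 1 lower of 10, the proliferation list 11 higher and none lower of 15, and the naive and memory list 1 higher and 2 lower of 10. When IL-12 cells were weighted to the class shares of the control library, the log2 ratio of Ifng moved from 2.40 to 1.78, Nkg7 from 1.62 to 1.01, Gzmb from 1.13 to 0.54, Pdcd1 from 1.08 to 0.49, the median of the exhaustion list from 0.44 to -0.11 and that of the regulatory T cell list from 0.54 to -0.08. In the Th2 and Th17 list 3 members were higher and 2 lower of 8, and Gata3, a Th2 regulator, was 1.23-fold lower.

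Myeloid lists stood apart from these. Of 12 genes of alternatively activated macrophages 8 were lower and 2 higher (median -1.08, percentile 0), with Ccl24 2.87-fold lower and Vegfa, a blood vessel growth factor, 2.53-fold lower, while Spp1, osteopontin, was 2.20-fold higher. Of 12 neutrophil and suppressor myeloid genes 8 were lower and 1 higher (median -0.78), with Mmp9 4.03-fold lower and Cxcr2, the neutrophil chemokine receptor, 3.09-fold lower. The neutrophil share was also smaller, 45.5% of IL-12 against 64.3% of control cells. Within neutrophils the median of this list was -0.36 (percentile 2.3), against -0.39 over all measured genes of that class. Classically activated macrophage genes went both ways, 4 higher and 3 lower of 10, with Tnf 3.01-fold higher. Costimulation and checkpoint ligands were higher in 2 and lower in 2 of 10; Pdcd1lg2, which encodes PD-L2, was 2.22-fold higher (2.01 to 2.46) and Cd274, which encodes PD-L1, stood at 330.7 and 395.2 CPM. Dissociation stress genes were higher in 2 and lower in 4 of 12, Hspa1b being 4.14-fold lower. Haemoglobin genes, a sign of red cell RNA, had 2 members lower and 2 within 1.5-fold, none of them measured by the rule used here.

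The CXCR3 ligands were then followed by class. Macrophages held 71.2% of the Cxcl9 UMIs in the control library and 73.1% in the IL-12 library. In that class Cxcl9 was at 50.8 CPM in control and 195.8 in IL-12, 3.85-fold higher (3.32 to 4.50), Cxcl10 was 4.36-fold higher (3.59 to 5.33) and Cxcl11 4.29-fold higher (3.22 to 5.84). Neutrophils held 76.9% of the Cxcl10 UMIs in control and 51.8% in IL-12, and their Cxcl10 level was 2.27-fold higher (2.08 to 2.49). With each cell thinned to 1000 UMIs, a Cxcl9 UMI was seen in 3.67% (2.19 to 5.74) of 490 control macrophages and in 9.99% (8.54 to 11.6) of 1552 IL-12 macrophages; 84 and 150 shallower cells were left out. Without thinning the shares were 8.01% and 21.6%, at median depths of 5514 and 7211 UMIs. In CD8 T cells, which should lack the ligand, the thinned shares were 0.308% and 0.521%, at median depths of 5794 and 6434 UMIs.

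Cxcr3 UMIs came mainly from T cells. CD8 T cells held 74.5% of them in control and 63.2% in IL-12, CD4 T cells 18.2% and 23.3%. In the CD8 class Cxcr3 stood at 10.3 CPM and 18.8 CPM, 1.82-fold higher (1.32 to 2.58), and in the CD4 class at 20.1 CPM and 61.3 CPM, 3.04-fold higher (1.61 to 6.47). At 1000 UMIs per cell a Cxcr3 UMI was seen in 1.39% (0.636 to 2.62) of control and 1.84% (1.41 to 2.36) of IL-12 CD8 T cells, and in 2.81% (0.918 to 6.43) and 4.55% (3.32 to 6.05) of CD4 T cells. These intervals overlap, which does not decide whether the shares of Cxcr3-bearing cells differ, and no test of that difference was made. Unthinned shares in the CD8 class were 5.09% and 8.18%. The thinned share in neutrophils was 0.0383% and 0.0873%, at median depths of 2586 and 2602 UMIs. On the mm10 annotation the ligand genes lie side by side on the minus strand of chromosome 5, Cxcl9 from 92321347 to 92328079, Cxcl10 from 92346638 to 92348889 and Cxcl11 from 92359544 to 92365485, the last annotated as a polymorphic pseudogene. Cxcr3 lies on the minus strand of chromosome X from 101731535 to 101734269.

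**Figure D2:**
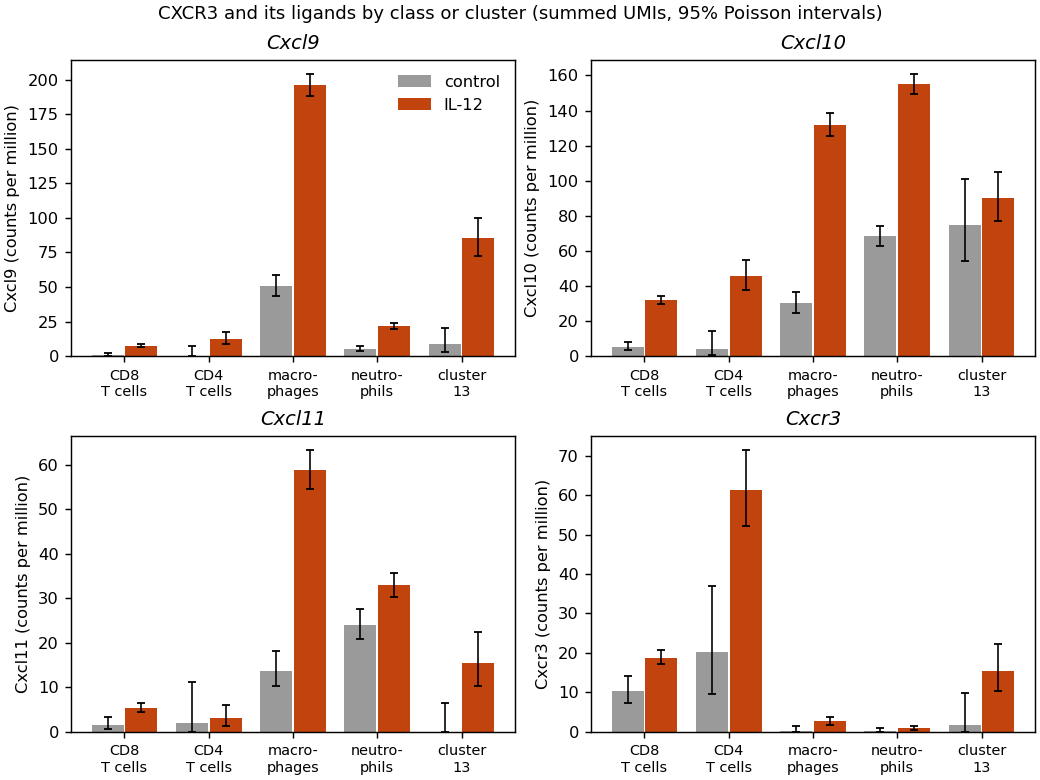
CPM from summed UMIs (vertical axes) of Cxcl9, Cxcl10, Cxcl11 and Cxcr3 in 4 of the authors' classes and cluster 13 of the control library (grey) and the IL-12 library (orange), with 95% Poisson intervals that cover counting error only. Cxcl9 in macrophages stands at 50.8 and 195.8 CPM, and Cxcr3 is highest in the class called CD4 T cells, at 20.1 and 61.3 CPM.

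In the cells called CD8 T cells, effector cytokine and chemokine transcripts stood higher in the IL-12 library. Ifng was at 91.5 CPM in control and 291.6 in IL-12, 3.19-fold higher (2.87 to 3.55). Ccl3 and Ccl4, chemokines released by activated T cells and by myeloid cells, were 3.98-fold (3.70 to 4.29) and 3.83-fold higher (3.59 to 4.08), and Ccl5 was 2.94-fold higher (2.88 to 3.01). Without clusters 11 and 12, of which cluster 12 carried neutrophil transcripts, the log2 ratio moved from 1.99 to 1.10 for Ccl3 and from 1.93 to 1.26 for Ccl4, and stood at 1.80 for Ifng, against 1.66 with them. Gzmb, the gene of granzyme B, was 1.26-fold higher (1.22 to 1.30) and Pdcd1 1.24-fold higher (1.18 to 1.29). Different clusters held this class in the libraries. Cluster 8 held 572 of the control cells and 67 of the IL-12 cells, cluster 5 held 21 and 2488, and cluster 12 held 54 and 706. Over both libraries the 10 leading genes of cluster 8 included Ikzf2 and Gzma, markers of regulatory T cells and NK cells, and no CD8 marker. Within the control library they included Cd8a and Cd3g. Values by cluster number therefore stand beside those of the class. Of the cluster's 639 cells, 77.8% held a Cd8a UMI, 89.2% Cd3e, 59.5% Ikzf2, 18.9% Gzma, 1.88% Foxp3 and 2.35% Ncr1. Klre1, a further NK cell marker, was seen in 19.1%, and Cd4 in 11.9%, or 12.9% of control and 2.99% of IL-12 cells. The ranking was made against cells outside the CD8 class, many of which, in the CD4 class, also held Cd8a. Over both libraries, clusters made here at resolution 1 placed 7.69% of the CD8 class with CD4 T cells and 4.17% with NK cells. Levels of the class, such as those of Cd4, Gata3 and Ikzf2, were not separated from this make-up. Between cluster 8 of the control library and cluster 5 of the IL-12 library, Ifng was 3.51-fold higher (3.13 to 3.95), Gzmb 1.37-fold higher (1.32 to 1.41) and Cxcr3 2.07-fold higher (1.43 to 3.10). Within cluster 12 Ifng was 2.40-fold higher (1.73 to 3.43) and within cluster 8 it was 1.84-fold higher (1.33 to 2.49).

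Of the ranked genes of this class, the highest were Mcpt2 at 32.9-fold (14.1 to 101.5) and Mcpt1 at 18.3-fold, then Gpx4 at 11.9-fold, Atp6v0c-ps2 at 10.2-fold, Hcar2, a receptor of hydroxybutyrate and niacin, at 8.71-fold (7.48 to 10.2), Tpt1-ps6, Rbx1-ps and Dnajc19-ps. Ifit1bl2 had 3 UMIs in control, giving a 14.2-fold difference (4.79 to 69.1), and Zbed5 was 6.90-fold higher. Hcar2 is also the leading gene of neutrophil cluster 2 in both libraries, and without clusters 11 and 12 its log2 ratio moved from 3.09 to 1.40, that of Ifit1bl2 from 2.74 to 0.93, that of Mcpt2 from 4.23 to 2.89 and that of Mcpt1 from 3.86 to 2.09. The lowest were Sema6d, a semaphorin (interval of the lower fold 5.63 to 8.71), Ttn, Insyn2b, Atp8b2, the X-inactivation RNA Xist at 5.71-fold lower (5.30 to 6.16), Tnfsf8, the CD30 ligand, at 5.08-fold lower, Epas1, a hypoxia-inducible transcription factor, at 4.93-fold lower, Cd4 at 4.66-fold lower (3.98 to 5.45), Irf2bp2 and Lars2.

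Cytotoxic effector genes were higher in 7, lower in 2 and within 1.5-fold in 3 of 12 in this class (median 0.69, percentile 96.2), against a median of -0.31 over its 6855 measured genes. In the T cell attracting chemokine list 7 were higher and 1 lower of 10 (median 1.96), Cxcl10 being 6.02-fold higher (3.91 to 9.79); its log2 ratio moved from 2.38 to 1.64 without clusters 11 and 12. Proliferation genes were higher in 9 and lower in none of 15 (median 0.76, percentile 100), among them Rrm2, a subunit of ribonucleotide reductase, at 3.35-fold (2.21 to 5.34), Birc5 at 2.48-fold and Cdk1 at 2.11-fold. The IL-12 signalling list had 1 higher and 4 lower of 10 (median -0.41, percentile 19.7): Il18r1, a chain of the interleukin 18 receptor, was 2.44-fold lower (2.16 to 2.76), Stat4, which transmits the IL-12 signal, 1.97-fold lower (1.77 to 2.18) and Il12rb2 1.69-fold lower. The naive and memory list had 1 higher and 5 lower of 10 (median -0.59, percentile 19.0), with S1pr1, needed for exit from lymphoid tissue, 3.45-fold lower and Tcf7, a factor of stem-like T cells, 2.69-fold lower (2.20 to 3.29). Exhaustion genes were higher in 2 and lower in 3 of 10 (median -0.18, percentile 23.5): Cd160 was 2.18-fold higher, Tox 1.70-fold lower and Nr4a2 2.08-fold lower. The regulatory T cell list had 1 higher and 2 lower of 10 (median -0.30, percentile 19.3), with Ikzf2 at 3.04-fold lower (2.87 to 3.23) and Ccr8 at 1.71-fold higher. In the Th2 and Th17 list 2 were higher and 3 lower, Gata3 being 2.41-fold lower.

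Interferon and antigen presentation lists were mixed in the CD8 class. Type I interferon response genes were higher in 11 and lower in none of 14 (median 1.28, percentile 100), with Rsad2 4.56-fold (3.75 to 5.60), Usp18 3.20-fold and Isg15 2.93-fold (2.75 to 3.11) higher. Interferon-gamma response genes were higher in 7 and lower in 3 of 21 (median 0.01, percentile 67.5); Gbp2 was 2.28-fold higher and Irgm2 1.75-fold lower. MHC class I genes were higher in 4 and lower in 1 of 11 (median 0.02, percentile 26.5), with H2-K1 1.86-fold and Psmb8 1.92-fold higher and Erap1 1.65-fold lower. MHC class II genes, more typical of myeloid and B cells, were higher in 4 and lower in 1 of 10, with H2-Eb1 2.67-fold and Cd74 2.47-fold higher. Myeloid lists also differed in this class. Of the classically activated macrophage genes 7 were higher and none lower of 9, with Il1b at 3.08-fold and Tnf at 3.21-fold, and of the neutrophil and suppressor genes 5 were higher and 1 lower of 12, with Arg2 at 3.84-fold and Clec4d, a myeloid lectin, at 2.91-fold. Alternatively activated genes were higher in 2 and lower in 4 of 9, with Spp1 2.62-fold higher and Vegfa 3.11-fold lower. Costimulation ligands were lower in 3 and higher in none of 10, with Pvr 2.69-fold lower, and stress genes were higher in 2 and lower in 3 of 12, with Atf3 3.56-fold higher and Hspa1b 3.22-fold lower.

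Cluster 12 carried neutrophil transcripts in both libraries: S100a8, a calprotectin subunit, stood there at 21253 CPM in control and 15799 in IL-12, a gene chosen after its values were seen, and a doublet caller marked 1 of its 54 control cells and 59.6% of its 706 IL-12 cells, at score thresholds of 0.570 in the control library and 0.209 in the IL-12 library. With clusters 11 and 12 left out, the log2 ratio in the CD8 class moved from 2.15 to 0.67 for Rsad2, from 1.90 to 0.85 for Arg2, from 1.18 to 0.48 for Gbp2, from 1.55 to 0.82 for Isg15, from 1.62 to 0.64 for Il1b and from 1.53 to 0.31 for Clec4d. It changed sign for Tnf (1.66 to -0.12), Atf3 (1.79 to -0.10), Fos (1.30 to -0.35) and Wfdc17 (0.76 to -1.04). The median of the type I interferon list moved from 1.28 to 0.80, that of the classically activated list from 1.37 to 0.15 and that of the neutrophil and suppressor list from 0.48 to -0.71. All 4 members of the CXCR3 list were higher in the CD8 class (median 1.60), and haemoglobin genes were lower in 2 of 2 cases, with Hba-a1 at 25.5-fold lower (16.7 to 40.3). A UMI of S100a8 was seen in 95.5% of control and 55.9% of IL-12 cells of the class. Whether such UMIs were free RNA from neutrophils was not tested, in this class or in any other.

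The CD4 class held 179 control and 998 IL-12 cells, and T cell markers in it differed between the libraries. Cd3d had a UMI in 52.5% (44.9 to 60.01) of control and 73.4% (70.5 to 76.1) of IL-12 cells, Lat, a signalling adaptor of T cells, in 39.1% (31.9 to 46.7) and 57.2% (54.1 to 60.3), and a receptor was recorded for 17.9% and 53.9%; neutrophils stood at 3.27% and 6.08% for Cd3d and 0.698% and 2.51% for Lat, at the depths given above. Within the control library the leading gene of cluster 9, which holds this class, was Il1rl1, the interleukin 33 receptor. These genes were chosen after their values were seen. Ifng stood at 46.3 CPM and 179.7 CPM, 3.88-fold higher in IL-12 (2.56 to 6.18). Gzmb was 2.09-fold higher (1.78 to 2.46), Gzmk, granzyme K, 3.21-fold higher (2.09 to 5.18) and Ccl5 stood at 4556 and 9133 CPM. Cd8a was at 428.6 and 490.7 CPM in this class and Cd4 had 40 and 176 UMIs, a log2 ratio of -0.26 whose interval includes no difference. In the 32 control and 538 IL-12 cells of the class with a receptor, the log2 ratio was 1.10 in place of 1.93 for Ifng, 0.52 in place of 1.06 for Gzmb and -0.72 in place of -0.85 for Gata3, the median of the cytotoxic list 0.55 in place of 0.85, and that of the MHC class II list turned to -0.06 from 1.06. Of 12 cytotoxic effector genes 7 were higher and none lower (median 0.85, percentile 99.99), against a median of -0.02 over 4644 measured genes. Type I interferon genes were higher in 10 and lower in 1 of 12 (median 1.18), with Rtp4 at 3.25-fold (1.82 to 6.39) and Ifit1 at 2.49-fold. Interferon-gamma response genes were higher in 6 and lower in 3 of 19, with Gbp2 3.56-fold higher and Irf1, an early interferon-induced factor, 2.49-fold lower (1.83 to 3.37). MHC class II genes were higher in 3 and lower in none of 7, Cd74 at 2.58-fold and H2-Eb1 at 2.24-fold, and MHC class I genes in 2 and none of 11, H2-K1 at 1.72-fold. Foxp3, the regulator that defines regulatory T cells, was 1.65-fold higher (1.01 to 2.86), and the regulatory list had 3 higher and 1 lower of 9.

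The remaining lists went both ways in the CD4 class. Exhaustion genes were higher in 3 and lower in 1 of 10, with Tigit 2.03-fold and Lag3 1.56-fold higher and Pdcd1 at 1.08-fold. IL-12 signalling genes were higher in 2 and lower in 1 of 10, with Cxcr6 1.61-fold higher and Il18r1 1.76-fold lower. Proliferation genes were higher in 7 and lower in none of 10, naive and memory genes in 1 and none of 9, and T cell attracting chemokines in 4 and none of 7. Th2 and Th17 genes were higher in 2 and lower in 3 of 5, with Gata3 1.81-fold lower. Stress genes were lower in 6 and higher in none of 12, with Dnajb1 1.88-fold lower. Neutrophil genes were lower in 4 and higher in 2 of 9 (median -1.31, percentile 0), S100a8 being 4.55-fold lower (4.07 to 5.09) with a UMI in 95.5% of control and 42.5% of IL-12 cells. Levels of neutrophil genes in this class were not separated from free RNA of neutrophils. The costimulation list had 1 higher and 2 lower of 7, with Cd274 1.57-fold lower (1.12 to 2.17). Classically activated genes were higher in 4 and lower in none of 7, and alternatively activated genes in 2 and 2 of 6, both lists with few UMIs. All 3 members of the CXCR3 list with 20 UMIs were higher; Cxcl9 had 0 and 33 UMIs, at least 2.08-fold higher. The ranked genes rested on few control UMIs: Zbed5 had 3 (25.2-fold, 8.57 to 122.8), Mcpt1, Ms4a6d, Cnot2 and Ube2n-ps1 had 1 each, and Mcpt2, Rbx1-ps and Ccl8 had 2 each. Gpx4 was 14.7-fold (7.41 to 34.2) and Tpt1-ps6 8.23-fold higher. The lowest were Cstdc5 and Retnlg, both of neutrophils, at 6.61-fold and 6.02-fold lower, Hk2, S100a8, Mir142hg, Nphs1 at 4.08-fold lower (3.60 to 4.62), Naa10, Vamp1, Man2a2 and Rnu3b3.

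Macrophages of the IL-12 library stood higher in interferon-gamma-inducible and antigen presentation genes and lower in genes of alternative activation. Iigp1 was 5.94-fold (4.46 to 8.09), Gbp4 3.61-fold and Gbp2 2.66-fold higher. The interferon-gamma response list had 13 higher, 1 lower and 7 within 1.5-fold (median 0.81, percentile 100), against a median of -0.11 over 6328 measured genes. H2-Aa, a chain of MHC class II, was 2.20-fold higher (2.16 to 2.25), Cd74, its chaperone, 2.12-fold, and Cd40, a costimulatory receptor, 2.54-fold. The MHC class II list had 7 higher and 1 lower of 10 (Cd80, 1.76-fold lower), and the MHC class I list 5 higher and none lower of 11, with H2-K1 at 2.31-fold and B2m at 2.08-fold. Type I interferon genes were higher in 9 and lower in none of 14, with Rtp4 at 2.85-fold and Isg15 at 2.23-fold. All 4 CXCR3 genes were higher (median 2.02). Cxcl9 was higher within each macrophage cluster, 3.76-fold (3.23 to 4.41) in cluster 6, which held 368 control and 1174 IL-12 cells, and 5.45-fold (2.79 to 12.2) in cluster 10, which held 209 and 519.

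Chil3 was at 1783 CPM in control macrophages and 203.2 in IL-12 macrophages, 8.78-fold lower (8.38 to 9.20). It was 11.7-fold lower (10.4 to 13.1) in neutrophils, at 214.6 and 18.4 CPM. S100a8, a neutrophil transcript, had a UMI in 95.6% of control and 64.8% of IL-12 macrophages, at median depths of 5514 and 7211 UMIs, against 99.8% and 97.1% of neutrophils, and its level in macrophages was 1.23-fold lower (1.21 to 1.26). Mrc1, the mannose receptor, was 2.45-fold lower (2.20 to 2.74), Ccl24 2.78-fold and Vegfa 2.48-fold lower (2.34 to 2.64); the alternatively activated list had 7 lower and 2 higher of 12 (median -1.28, percentile 0). The classically activated list had 4 higher and 3 lower of 9, with Tnf 2.47-fold higher and Il6 2.89-fold lower (2.51 to 3.32). Neutrophil and suppressor genes were higher in 2 and lower in 3 of 12, with Arg2 2.17-fold higher and Mmp9 2.56-fold lower. The T cell attracting chemokines were higher in 5 and lower in none of 10. Costimulation ligands were higher in 5 and lower in 2 of 10, with Pdcd1lg2 2.77-fold higher and Cd274 1.15-fold. Proliferation genes were higher in 2 and lower in 4 of 14, with Tyms 1.75-fold and Mki67 1.66-fold lower, and stress genes were higher in 2 and lower in 3 of 12, with Egr1 1.76-fold higher and Hspa1b 2.99-fold lower. The lowest genes of the ranking included Ear2, an eosinophil-type ribonuclease also made by alveolar macrophages, at 21.8-fold lower (14.0 to 35.4), Car4, a carbonic anhydrase, at 19.2-fold lower (13.1 to 29.1), Adamdec1, Chil3, Plet1 at 8.66-fold lower (6.81 to 11.1), Mt2, a metallothionein, Gpx3, Rn7s2 and Net1.

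Lists of T cell genes also stood higher in the IL-12 macrophages. Cytotoxic effector genes were higher in 9 and lower in 1 of 12 (median 1.93), with Prf1, perforin, at 6.78-fold (3.90 to 12.9), Nkg7 at 5.46-fold and Ccl5 at 4.90-fold. Exhaustion genes were higher in 6 and lower in none of 10, with Ctla4 at 11.6-fold (6.56 to 22.6) and Pdcd1 at 4.58-fold, the regulatory list in 8 and none of 9, the IL-12 signalling list in 6 and none of 10, with Cxcr6 at 5.88-fold, and the naive and memory list in 4 and 1 of 10. All 3 Th2 and Th17 genes with 20 UMIs were higher, and 2 of 4 haemoglobin genes were lower. Ifng had 5 control UMIs and was 12.2-fold higher (5.12 to 37.8). T cell receptor sequences were recorded for 2.09% (1.08 to 3.62) of control and 10.2% (8.82 to 11.8) of IL-12 macrophages. Without the macrophages that had a receptor, the log2 ratio moved from 2.46 to 1.75 for Prf1, from 2.42 to 1.90 for Nkg7, from 1.97 to 0.99 for Tigit and from 1.23 to 0.03 for Cd4, and the median of the cytotoxic list from 1.93 to 1.31. The other genes at the top of the ranking were Ap3s1-ps1, with 2 control UMIs and a 28.6-fold difference (7.80 to 237.6), Calhm6 at 9.96-fold, Ly6c2 at 8.39-fold (7.39 to 9.56), Atp6v0c-ps2, Ly6a at 7.97-fold, Serpina3f, a serine protease inhibitor, Gimap7, a lymphocyte GTPase, and Tpt1-ps6.

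In neutrophils, interferon-inducible genes, chemokines and Tnf stood higher in the IL-12 library, and Retnla, Chil3 and Mmp8 lower. Isg15 was at 1940 CPM in control and 5386 in IL-12, 2.78-fold higher (2.73 to 2.82), Gbp4 was 11.4-fold higher (9.89 to 13.2) and Tnf 4.59-fold higher (4.37 to 4.82). Cd274 was at 481.2 and 832.4 CPM, 1.73-fold higher (1.67 to 1.79). Retnla, a resistin-like protein of type 2 responses, was 52.4-fold lower (40.8 to 68.4), with a UMI in 6.54% of control and 0.762% of IL-12 neutrophils, and Mmp8 was 4.54-fold lower (4.29 to 4.80). Different clusters held most of the class: clusters 1 and 4 held 1263 and 552 control cells against 165 and 26 IL-12 cells, and clusters 2 and 3 held 1914 and 2606 IL-12 cells against 427 and 27 control cells. Type I interferon genes were higher in 11 and lower in 1 of 13 (median 1.33, percentile 100), with Ifit2 at 4.22-fold and Ifit3 at 3.74-fold. The median over the 3351 measured genes was -0.39, and scaling to that median moved the list to 1.72. Interferon-gamma response genes were higher in 11 and lower in 3 of 21, with Icam1 3.09-fold higher and Nos2 2.34-fold lower. MHC class I genes were higher in 5 and lower in none of 11, B2m at 2.85-fold, and MHC class II genes in 8 and 1 of 10, H2-Eb1 at 3.08-fold. T cell attracting chemokines were higher in 6 and lower in none of 10, with Ccl8 at 3.76-fold and Ccl4 at 3.02-fold (2.98 to 3.06).

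Neutrophil and suppressor genes were higher in 3 and lower in 4 of 12 in this class, with Retnlg 3.25-fold, Mmp9 2.92-fold and Cxcr2 2.34-fold lower. Alternatively activated genes were lower in 4 and higher in 1 of 9, with Spp1 3.65-fold higher, and classically activated genes higher in 5 and lower in 2 of 9, with Il1b 1.58-fold higher. Costimulation ligands were higher in 3 and lower in 2 of 9, with Pdcd1lg2 2.76-fold higher and Icosl 2.36-fold lower. Stress genes were higher in 5 and lower in 4 of 12, with Atf3 3.09-fold and Fos 2.80-fold higher and Hspa1b 4.67-fold lower. Proliferation genes were higher in 8 and lower in none of 14, few of them measured. T cell lists rested on low levels in neutrophils: cytotoxic genes were higher in 9 and lower in 2 of 11, IL-12 signalling genes in 5 and 3 of 8, exhaustion genes in 5 and 2 of 9, regulatory genes in 4 and none of 8, and naive and memory genes in 5 and 1 of 8. Th2 and Th17 genes were higher in 1 and lower in 2 of 3, and haemoglobin genes lower in 2 of 2. Of the CXCR3 list 2 members were higher, Cxcl9 at 4.01-fold (2.95 to 5.56) and Cxcl10 at 2.27-fold, and Cxcl11, at 1.37-fold, lay within 1.5-fold. The other genes at the top of the ranking were Mcpt2, with 8 control UMIs (38.5-fold, 19.4 to 89.6), Gbp8 at 15.2-fold, Mcpt1, Atp6v0c-ps2, Tpt1-ps6, H2-T10, Batf2, an interferon-induced transcription factor, at 8.48-fold, Csf3, the neutrophil growth factor G-CSF, at 7.43-fold (6.09 to 9.15), and Ifit1bl2. The lowest after Retnla were Chil3 at 11.7-fold lower, Klhl6, Crispld2, Adora3, Sgms1, Ecm1, Klhl2, Prnp and Fbxl5.

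**Figure D3:**
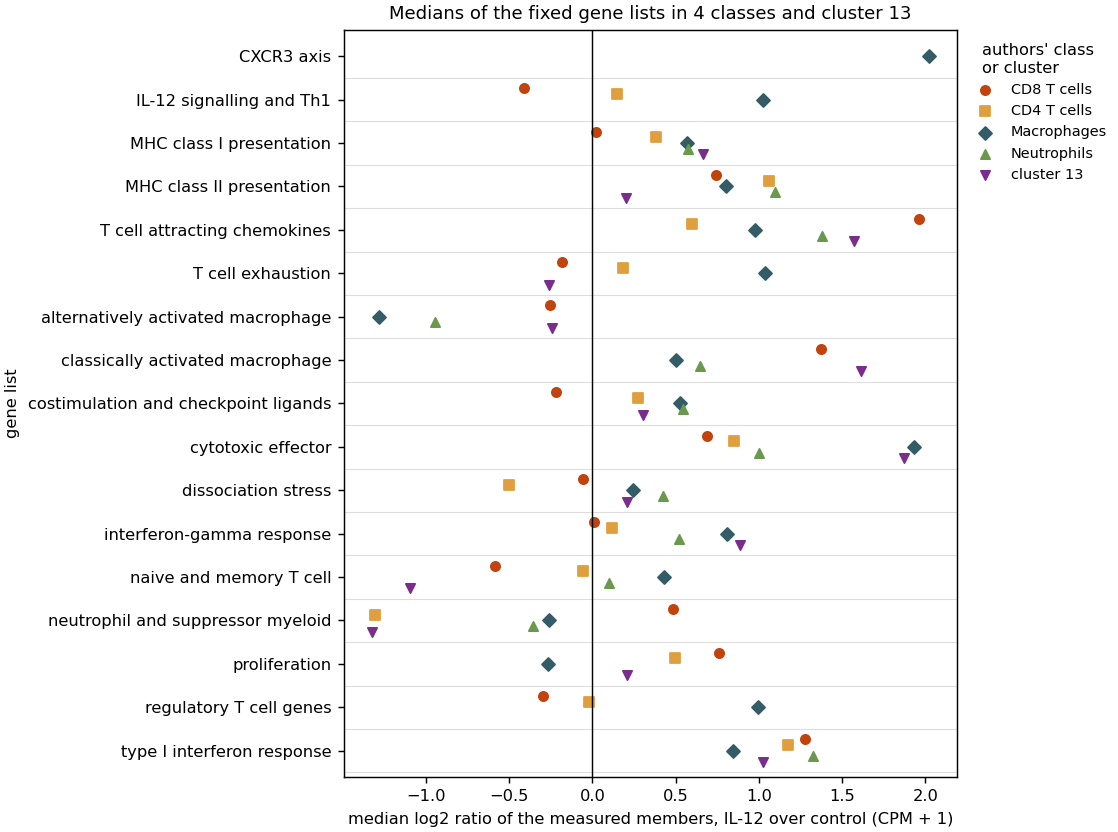
Median log2 ratio of IL-12 over control (horizontal axis, CPM plus a pseudocount of 1) of the measured members of each fixed gene list (vertical axis), with a symbol for each of 4 classes given by the authors and for cluster 13; lists with fewer than 3 measured members in a set of cells have no symbol there. The type I interferon list lies above 0 in all 4 classes and in cluster 13, and the alternatively activated list is lowest in macrophages at -1.28.

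Cluster 13, which the authors call B cells, held 95 control and 267 IL-12 cells. The class held 95 and 265, but 4 of its control cells lay outside the cluster, and 4 control and 2 IL-12 cells of the cluster are called neutrophils. Its 10 leading genes within the IL-12 library held 2 B cell markers, Cd79a and Cd79b, and 4 markers of other types, Klk1, Krt18, Fscn1 and Cox6a2, so levels are given for the cluster by its number and not for B cells. Its make-up differed between the libraries. In cells thinned to 1000 UMIs, Ighd, an immunoglobulin chain of naive B cells, had a UMI in 32.6% (23.4 to 43.0) of 95 control and 4.14% (2.08 to 7.28) of 266 IL-12 cells, and Ighm, a further chain, in 63.2% (52.6 to 72.8) and 30.8% (25.3 to 36.8). Siglech, a gene of plasmacytoid DCs, had one in 2.11% (0.256 to 7.40) and 9.02% (5.87 to 13.1), intervals that overlap. Without thinning these shares were 53.7% and 9.74% for Ighd, 69.5% and 49.8% for Ighm and 2.11% and 11.2% for Siglech, at median depths of 4342 and 6307 UMIs. Thinned neutrophils, which should lack all 3 genes, showed at most 0.613%, at median depths of 2586 and 2602 UMIs before thinning. These 3 genes were chosen after their values were seen, and the levels below were not separated from this make-up.

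Il12b stood at 10.5 CPM in control and 195.6 in IL-12 in cluster 13, 18.7-fold higher (8.50 to 51.3), and the cluster held 354 of the 368 Il12b UMIs of the IL-12 library, or 96.2%. These UMIs lay in few cells, 1 of 95 in control (1.05%, 0.0267 to 5.73) and 19 of 267 in IL-12 (7.12%, 4.34 to 10.9). The interval of the fold treats UMIs as independent and is too narrow for UMIs held by so few cells. Mcpt1 and Mcpt2 each had 1 control UMI against 3754 and 2608 in IL-12, and 5 IL-12 cells of the cluster held 98.9% of the summed UMIs of both genes. Cd300a had 0 and 94 UMIs, at least 9.92-fold higher. Among the lowest genes, Retnlg, a neutrophil gene, was 66.04-fold lower (37.1 to 129.5), Cstdc5 was 42.9-fold lower (20.01 to 109.5), and Cstdc6 had 72 and 1 UMIs. S100a8, a neutrophil transcript, had a UMI in 97.9% (92.6 to 99.7) of control and 40.1% (34.2 to 46.2) of IL-12 cells of the cluster. Levels of neutrophil genes in the cluster were not separated from free RNA of neutrophils. Neutrophil and suppressor genes were lower in 6 and higher in 2 of 11, with a median of -1.33 in the cluster and -0.17 over the same genes in the class called B cells. Interferon-gamma response genes were higher in 11 and lower in 1 of 20, with Igtp 4.02-fold higher (2.46 to 7.04). Type I interferon genes were higher in 8 and lower in none of 10, classically activated genes in 5 and 1 of 9, and T cell attracting chemokines in 7 and 1 of 10, with Cxcl9 at 9.76-fold (4.09 to 30.5). Naive and memory genes were higher in 2 and lower in 6 of 9, and MHC class II genes were higher in none and lower in 1 of 10 (Ciita, 3.60-fold lower). The class called DCs, with 14 control cells, was not compared in level.

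T cell receptor clones were counted to set the CD8 T cell share beside its clonal make-up. Receptors were recorded for 497 control and 3592 IL-12 cells. Among CD8 T cells 69.2% (65.5 to 72.7) of control and 86.3% (85.1 to 87.5) of IL-12 cells had a receptor, and among CD4 T cells 17.9% (12.6 to 24.3) and 53.9% (50.8 to 57.0). The control cells formed 204 clones, 45 of them with at least 2 cells, and the IL-12 cells 771 clones, 137 of them with at least 2 cells. Clones of 2 or more cells held 68.0% (63.7 to 72.1) of control receptor cells and 82.3% (81.1 to 83.6) of IL-12 receptor cells. More cells make a repeated clone more probable to be seen. Over 1000 draws of 497 IL-12 cells the share was 75.1%, with 95% of draws between 71.2% and 78.7%, and the number of clones was 151 (134 to 169). At that number the Shannon index, which rises with the number and evenness of clones, was 3.53 (3.35 to 3.72) in IL-12 and 4.29 in control.

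The largest clone held 101 control cells, or 20.3%, with the CDR3 pair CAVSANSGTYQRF (alpha chain) and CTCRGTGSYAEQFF (beta chain). The next control clones, of 39 and 17 cells, held that alpha chain alone and that beta chain alone. With clones drawn from the beta chain alone, the largest held 118 of 389 control cells, or 30.3%, and 822 of 3388 IL-12 cells, or 24.3%; the cells formed 142 and 599 clones, with Shannon indices of 3.74 and 3.44, and clones of 2 or more cells held 72.0% (67.2 to 76.4) and 85.7% (84.5 to 86.9). Over draws of 389 IL-12 cells this share was 78.4% (74.6 to 82.0) and the Shannon index 3.01 (2.81 to 3.21). The largest IL-12 clones, as drawn by the authors, held 669 cells, or 18.6% (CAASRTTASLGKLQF and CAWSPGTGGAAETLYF), 662 cells (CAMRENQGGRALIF and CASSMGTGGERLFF) and 286 cells (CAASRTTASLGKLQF and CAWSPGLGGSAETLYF). The first and last of these share the alpha chain, and whether they are separate clones was not tested. If they are the same clone, the IL-12 shares given here for the largest clone are too low. Of 203 CDR3 sets in control and 759 in IL-12, 3 were found in both libraries, in 44 control and 4 IL-12 cells. Within the CD8 class clones of 2 or more cells held 69.7% (65.2 to 73.9) of 449 control and 87.7% (86.4 to 88.8) of 2817 IL-12 receptor cells, or 81.3% (78.0 to 84.4) over draws of 449 IL-12 cells.

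**Figure D4:**
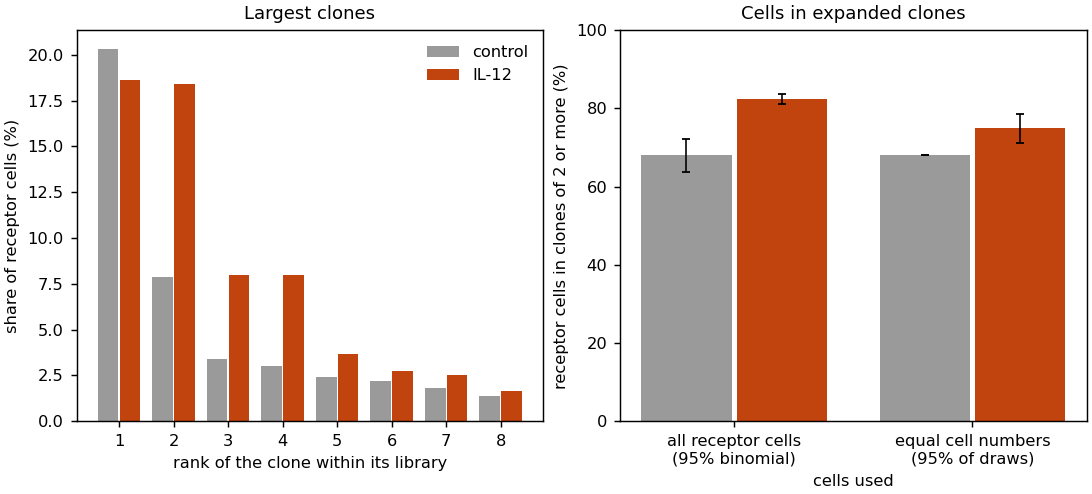
Left, share of receptor cells (percent) in each of the 8 largest clones of the control library (grey) and the IL-12 library (orange), by rank. Right, share of receptor cells in clones of 2 or more cells, 68.0% and 82.3% over all receptor cells (bars: 95% binomial intervals) and 68.0% and 75.1% at equal cell numbers (bar: 95% of 1000 draws; the control value is drawn without a bar).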

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

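The test of shared gene copies on the 11 genes below was chosen before its result was seen; all other tests of this part were chosen after. Cd4 was higher in IL-12 macrophages (log2 ratio 1.23, from 4 and 47 UMIs) and lower in IL-12 CD8 T cells (-2.15), opposite directions in different classes whose difference was not tested. Cd274 was higher in neutrophils (0.79) and lower in CD4 T cells (-0.65), and this difference was not tested either. Receptor sequences, which belong to T cells, were recorded for 10.2% of IL-12 macrophages. The class called DCs, which no level comparison uses, made up 6.49% of the IL-12 library.

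The first pattern is a set of 11 genes among the 10 highest in at least 2 of 5 comparisons: Atp6v0c-ps2, Gpx4, H2-T10, Ifit1bl2, Ly6a, Ly6c2, Mcpt1, Mcpt2, Rbx1-ps, Tpt1-ps6 and Zbed5. Their median share of 60-base stretches found in another gene was 14.1 percentage points above that of 4458 genes of like level, between the bounds set for and against shared copies. Reads shared with near-identical copies and the IL-12 plasmid, with 1 library per treatment, therefore cannot be told apart by this test. Measured genes named as pseudogenes, 56 in number, had a median log2 ratio of 0.72, against -0.11 for 3098 genes without shared stretches. Over all sorted cells the parent genes Tpt1 (-0.01), Rbx1 (0.12) and Atp6v0c (-0.42) did not rise with their pseudogenes. No bounds were set for these values, which do not cover the other genes of the pattern. Free RNA of a common source is argued against for the genes other than Mcpt1 and Mcpt2, since 9 of 9 differed 2-fold or more between CD8 T cells, CD4 T cells, macrophages and neutrophils. For Mcpt1 and Mcpt2 free RNA from other cells is a candidate explanation: their levels in these 4 classes lay within 1.73-fold, and cluster 13 stood at least 23.2 times above the highest. Of the 8 IL-12 cells with at least 100 UMIs of both genes, only 5 lay in cluster 13. The others were not left out of the levels compared. Like levels point to free RNA only if it scales with a cell's depth, which was not checked. Shared copies are argued against for these 2 genes, with 0% of their stretches found elsewhere.

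The next pattern is T cell transcripts in IL-12 macrophages. With free RNA alone, and in proportion to a cell's depth, thinned macrophages and neutrophils would show Cd3e alike. A UMI was seen in 7.22% (5.98 to 8.62) of macrophages and 2.95% (2.53 to 3.42) of neutrophils, a ratio of 2.45. In the control library the shares were 2.65% (1.42 to 4.49) and 1.19% (0.808 to 1.68). Macrophages without a receptor stood at 4.27% (3.26 to 5.47) in IL-12, near the neutrophils, so free RNA stays open for them. Their median depth was 7322 UMIs against 2602 in neutrophils. How free RNA scales with depth was not checked, so this comparison cannot decide. Doublets of a macrophage and a T cell are a candidate explanation for those with a receptor, which held a median of 11652 UMIs against 6380, a ratio of 1.83, and a Cd3e UMI, without thinning, in 92.5% against 13.1%. No biological explanation was tested.

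The last pattern is cluster 11 of the IL-12 library, which holds most cells called DCs. A UMI of a DC marker was seen in 19 of its 731 thinned cells (1.57% to 4.03%), above the 0.751% (0.544 to 1.01) of neutrophils and beside the 2.06% (1.41 to 2.90) of macrophages, and in 24.4% (19.4 to 30.1) of cluster 13, a ratio of 0.106, which argues against a cluster made mainly of DCs, while a small share of DCs stays open. Cells drawn from several classes stay open. Own clustering placed 81.4% of the cluster, or 681 of 837 cells, with macrophages at resolution 1. The share was 81.5% at resolution 2 and 81.0% with each library on its own, but 86.7% went with CD8 T cells at resolution 0.5. Without thinning, the cluster held transcripts of T cells (Cd3e in 49.9% of cells, Cd8a in 44.2%), neutrophils (G0s2, 76.3%) and macrophages (C1qc, 38.1%). Adgre1, a further macrophage gene, was seen in 5.02%, and a receptor was recorded for 6.09%. These genes were chosen after their values were seen, and whether such UMIs were free RNA was not tested. Damaged cells are a candidate explanation: the median mitochondrial share was 2.13% against 1.06% in the rest of the library, a ratio of 2.01, at 1859 against 3652 UMIs. No biological explanation besides DCs was tested.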

How the results depend on the processing

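Settings with own clustering at resolution 1, without clusters 11 and 12, with receptor cells alone or without them, the CD8 to CD4 ratio with each library on its own, the class called B cells in place of cluster 13, and equal cell numbers in the CD8 class or for beta chain clones were chosen after the data were seen; the rest were planned. Of 4956 values for 610 results under the alternatives, leaving out those that answer a comparison directly, 3716 stayed within their counting interval, 1220 left it, and 20 turned from a value of 1.5-fold or more, or from a share difference whose interval excludes 0. Counting turns from smaller values too, 114 changed sign; the cause was not tested. No paired analysis was possible because each treatment had 1 pooled library. The filter of 500 UMIs and 10% mitochondrial UMIs removed 0 cells and says nothing; the doublet caller marked 2 control and 570 IL-12 cells, at differing score thresholds, so leaving doublets out acts mainly on the IL-12 library. The CD8 share difference of 9.81 points was 7.54 without doublets, 18.1, 13.7 and 13.8 with own clusters at resolutions 0.5, 1 and 2, 15.4 with each library clustered on its own, 19.1 from marker UMIs, 3.21 without neutrophils and 8.10 without clusters 11 and 12. The neutrophil difference of -18.8 points was -16.9 without doublets and -13.7 without clusters 11 and 12. The CD4 difference of 3.46 points turned to -1.05 with each library on its own and -0.156 from marker UMIs, and was 0.480, 0.908 and 0.713 at resolutions 0.5, 1 and 2. The log2 ratio of the CD8 to CD4 ratios, -0.15, turned to 1.34 from marker UMIs, 0.93, 0.67 and 0.66 at resolutions 0.5, 1 and 2, and 1.48 with each library on its own. Trimmed mean of M-values and median-of-ratios scaling gave Ifng in CD8 T cells 2.02 and 1.98 in place of 1.66 (1.45 in cells with a receptor), the cytotoxic list there 1.04 and 1.01 in place of 0.69, and the type I interferon list in neutrophils 1.62 and 1.72 in place of 1.33. That list was 1.25 with a pseudocount of 10 CPM, 1.26 from cell means and 1.06 without the filter. A pseudocount of 10 CPM gave Cxcl9 in all cells 1.34 in place of 1.77 and the CXCR3 list in macrophages 1.76 in place of 2.02. Without clusters 11 and 12, Atf3 (-0.10), Tnf (-0.12), Fos (-0.35) and Wfdc17 (-1.04) turned in CD8 T cells; with cell means Tnfrsf18 (-0.030) and Tnfsf9 (-0.22) turned in macrophages and Ccl3 (-0.19) in cluster 13. In CD4 T cells with a receptor, 32 of them in control, Cxcl10 (-0.49), H2-Aa (-0.17), Fosb (0.094), Fos (0.28), Iigp1 (1.39) and the MHC class II list (-0.063) turned. Without the filter, which lets in genes with few UMIs, the Th2 and Th17 list turned to 0.048 in CD8 and 0.43 in CD4 T cells, the alternatively activated list to -0.24 in CD4 T cells, and in neutrophils the IL-12 signalling list to 0.47 and the exhaustion list to 0.40. The difference in macrophages with a Cxcl9 UMI, 6.31 points, was 13.6 without thinning and 11.2 at 2000 UMIs, since deeper cells show more genes. The difference in expanded clones, 14.3 points, was 7.04 at equal cell numbers, 6.43 at equal numbers with beta chain clones and 11.6 at equal numbers within the CD8 class.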

Other observations

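The genes and sequences of this part were chosen after their values were seen. Receptor sequences with shared ends stood in large clones of both libraries. The alpha chain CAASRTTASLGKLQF was recorded in 1112 IL-12 cells, or 31.0% of receptor cells. Of these, 687 had the beta chain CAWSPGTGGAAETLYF without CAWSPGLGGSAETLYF, 302 the converse and 98 both. Over all IL-12 receptor cells both beta chains met in 101 cells, against 111.5 if the chains were independent. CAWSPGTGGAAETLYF met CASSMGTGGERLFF, a beta chain of 740 cells, in only 10 cells. It met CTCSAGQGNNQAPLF, a beta chain of 343 cells, in 9. A shared clone with both beta chains, not always both recorded, therefore stays open and was not tested. In the control library, clones of 15 cells (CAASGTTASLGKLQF and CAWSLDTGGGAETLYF) and 7 cells (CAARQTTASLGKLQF and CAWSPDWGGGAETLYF) shared the end of the alpha chain and both ends of the beta chain with these. Such pairs made up 7.61% of control cells with 1 alpha and 1 beta chain, against 36.6% in the IL-12 library. The ends were read from these clones. The 955 IL-12 cells are the clones of 669 and 286 cells, so the shares restate clone sizes.

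Among macrophages, Ear2 had a UMI in 5.23% of control and 0.999% of IL-12 cells, and Car4 in 5.23% and 0.705%; whether these are the same cells was not tested. H2-Ea-ps, the annotation's name for the MHC class II E alpha gene, was at 466.3 CPM in control and 770.5 in IL-12 over all sorted cells, and 1.96-fold higher in IL-12 macrophages; C57BL/6 mice carry a promoter deletion of this gene. Cells with at least 100 UMIs of Mcpt1 and Mcpt2 numbered 8 in the IL-12 library and held 71.8% of the UMIs of both genes; Cpa3, a mast cell carboxypeptidase, stood at 115.5 CPM in cluster 13 of that library.

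Lars2, a mitochondrial leucyl-tRNA synthetase, was at 2492 and 824.6 CPM over all sorted cells, and Xist was 3.08-fold lower in the IL-12 library. The authors' labels put 32.9% of control and 47.9% of IL-12 receptor cells in S phase and 34.6% and 34.1% in G2M; cycling was not read from these labels. The authors' scores in 483 control and 3310 IL-12 receptor cells differed by 0.153 for activation (SD 0.297 and 0.452), 0.0153 for CXCR3 (SD 0.133 and 0.138) and -0.00311 for exhaustion (SD 0.182 and 0.185). Within the CD8 class, where the signs of the last 2 differ from these, the differences were 0.174, -0.00276 and 0.00419.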
